A study of Caenorhabditis elegans with 2 samples.

How the data were processed

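Anti-GFP ChIP-seq peaks of eGFP-tagged SNPC-1.2 from whole L4 larvae (48 hours, fragments of 200 to 800 bp per the labels) were taken from the deposited lists on assembly ce11. There were 2 samples, biological replicates 1 and 2 of 1 group, and 8 lists: 4 ranked lists of 20 columns and 4 thresholded lists in narrowPeak format, for each replicate and for the whole series. Per the file headers and notes, the lists were made from filtered alignments and a control. The peak caller, the aligner and their versions are not given in the sources used here. The deposited score is 125 times log2 of 1 over the global IDR, capped at 1000, which was worked out from the values. The deposited signal is the peak caller's signal value of the peak, with no scale stated, so it was compared within a list only. The ranked lists as deposited also hold the −log10 of the global IDR, capped at 5, and the signal value in each of the 2 sets of calls compared. From the values, one whole-series ranked list compares the true replicates and the other does not. Read depth is unknown, so intervals cover counting of genes or peaks only.

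Gene 5' ends came from Ensembl release 115 (WBcel235), and sequence from the matching RefSeq genome. No peak ended beyond its chromosome. The 13 mitochondrial peaks of the whole-series thresholded list were left out of all comparisons of genes and regions. The main list was the whole-series thresholded list, with each replicate's own thresholded list beside it. A gene was occupied when a summit lay within 250 bp of its 5' end. Classes were tested against protein-coding genes, and lists of protein-coding genes against all other protein-coding genes, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over all classes and lists and a threshold of 0.05. Shares carry exact 95% intervals (Clopper-Pearson). Of the SNAPc and TBP list 2 names, and of the piRNA pathway and splicing factor lists 1 name each, were not in the annotation. The snRNA genes were not split by U type.

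Peak overlap used 10000 circular shifts of a list along each chromosome. Medians of signal and of summit position were compared by two-sided permutation tests with 100000 resamples. The piRNA clusters were chromosome IV from 4.5 to 7.0 Mb and from 13.5 to 17.2 Mb, and their count was compared with 10000 circular shifts along the chromosome. Distances to piRNA genes used 1000 shifts of 1 to 20 kb, at distances of 50, 100, 250 and 500 bp, with the smallest p at 0.002. Ratios of medians inside and outside the clusters carry intervals from 10000 bootstrap draws. A ratio added after the data were seen took the same top share of all genes in both regions, set by the share occupied outside, with ranked signal values and 0 where there was no call. Unique sequence is the percent of 50-base words around a 5' end that occur once in the genome. Words of 8 bases on either strand within 75 bp of the summit were compared with flanks 500 bp away. For these the flanks held as many word positions as the summit window, in place of the same total length set beforehand. The B box and CTGTTTCA were counted in flanks of the same total length as the summit window, as set beforehand. Flanks in 2 pieces hold fewer positions for a word, so these counts were repeated, after the first values had been seen, with as many positions; all 5 results kept their call. With these flanks CTGTTTCA was at 14.9% of the flanks of piRNA peaks and 11.1% of those of all cluster peaks (adjusted p = 4.39e-08 and 0.000626, Fisher's exact test).

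The samples, the tests, the gene classes and lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names the 10 peaks with the highest signal value with the nearest 5' end. It also names up to 3 occupied genes with the highest signal in each of 8 RNA classes, and the 8 protein-coding genes with the highest peak and no non-coding RNA 5' end within reach. It adds every occupied SNAPc or TBP gene, up to 3 occupied genes of each list that passed the test, and snpc-1.2 itself; 1 gene that the rule names is not reported here. Alternatives were the conservative list, stricter IDR limits, the 500 highest peaks, windows of 100 and 500 bp, any overlap of the peak, circular shifts, 1 gene per locus, unique windows only, other overlap rules, a binomial test by length for the clusters, other word windows and flanks, and each replicate left out. The IDR limit of 0.01 removed no peak and is void; a limit of 0.001 was added after the lists were seen, as were the settings away from clusters or non-coding RNA genes.

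The procedures were tested on simulated data. Peaks planted at 60% of tRNA genes were recovered at 64.5%, since neighbouring genes share peaks, and those at 20% of ribosomal protein genes at 19.8%. Of 27 classes and lists given no peaks, 1 was called, the other non-coding RNA genes that neighbour tRNA genes. A planted signal fold of 2 came back as 1.98, a planted summit position of -50 bp as -50 bp, and random windows gave 0 words. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.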

Results

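Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done with an anti-GFP antibody on whole transgenic Caenorhabditis elegans larvae that express an SNPC-1.2-eGFP fusion protein. SNPC-1.2 is named as a subunit of the small nuclear RNA-activating protein complex (SNAPc), which binds promoters of small nuclear RNA genes. There was 1 group, larvae of the L4 stage at 48 hours, with 2 biological replicates. The whole-series list, made from both replicates, held 2842 peaks, of which 2829 lay on nuclear chromosomes with a median width of 340 bp and a covered length of 879 kb. Replicate 1's own list held 1428 peaks (1411 nuclear) and replicate 2's own list 1755 (1737 nuclear). The larger of these lists was 1.23 times the smaller, and the whole-series list was 1.03 times the conservative list of 2766 peaks. Read numbers per library are not given in the sources used here, so the depth behind each peak is unknown. No control library was analysed here, and there was no second condition, so the comparisons are between replicates, gene classes and regions.

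The replicates shared most of their nuclear peaks. Of replicate 1's peaks, 1036 of 1411 (73.4%, exact 95% interval 71.0 to 75.7) overlapped a replicate 2 peak. In the other direction 1033 of 1737 (59.5%, 57.1 to 61.8) overlapped. Circular shifts of one list along each chromosome gave means of 1.57% and 1.29%, and p = 0.0001 in each direction, the smallest that 10000 shifts can give (one-sided permutation test). Of the 2829 nuclear peaks of the whole-series list, 1306 (46.2%) overlapped a peak of replicate 1's own list and 1579 (55.8%) one of replicate 2's. Across the 83957 nuclear peaks of the ranked list, the replicates' signal values had a Spearman rho of 0.35 and a Pearson r of 0.38 on the log10 scale. Over the 5340 peaks with an irreproducible discovery rate (IDR) of at most 0.05, a set selected for agreement between the replicates, rho was 0.57 and r 0.84. These correlations run across peaks, which are not independent replicates, so no p-value is given.

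Genes for short structured RNAs were the most frequently occupied classes. A gene was counted as occupied when a peak summit lay within 250 bp of its 5' end. Of 18 genes for SL2 RNA, the trans-splicing leader of downstream genes in operons, 15 were occupied (83.3%, 95% interval 58.6 to 96.4), and the replicates' own lists gave 77.8% ± 7.86 (SD, n = 2). Of 612 nuclear tRNA genes, 405 were occupied (66.2%, 62.3 to 69.9; replicates 57.3% ± 0.578). Among 99 genes for snRNAs, the RNAs of the spliceosome and related particles, 42 were occupied (42.4%, 32.5 to 52.8; replicates 37.9% ± 0.714). Of 346 snoRNA genes, which guide chemical modification of other RNAs, 93 were occupied (26.9%, 22.3 to 31.9; replicates 24.4% ± 0.204). Protein-coding genes, the background, were occupied at 496 of 19973 (2.48%), with 1.22% in replicate 1 and 1.54% in replicate 2. Each of these classes therefore stood above the background by far more than the spread between replicates. Fisher's exact tests (two-sided, adjusted over 29 classes and lists) gave p = 3.90e-21 for SL2 RNA, 5.72e-39 for snRNA and 1.45e-62 for snoRNA genes. For tRNA genes the odds ratio was 76.8 and log10 of the raw p was -429, beyond what the software holds as a p-value.

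The strongest peaks named individual members of these classes. The highest nuclear signal value of the whole-series list, 3755, lay at the snoRNA gene Y67A10A.14 (IV, 14326948 to 14327121, minus strand), with 1713 in replicate 1 and 2025 in replicate 2. The tRNA-Pro gene F02H6.t1 followed with 2283 (1110 and 1174 in the replicates), and the snoRNA genes Y73F8A.1175, M03D4.78 and T08B6.64 with 2217, 2069 and 1874. The tRNA-Ala gene Y7A9D.t2 had 1438 and the tRNA-Val gene Y7A9D.t3 had 1376. Among snRNA genes the highest were Y57G11C.35 (1356), Y9C9A.111 (925) and smy-8 (838). Among SL2 genes they were sls-2.17 (1045), sls-2.12 (873) and sls-2.13 (681). The ranked list also held a peak of 3120 on chromosome X (IDR at most 0.01) that the thresholded list lacks. All of the 10 highest nuclear peaks of the thresholded list were on chromosome IV. The other 3 of these peaks had no short structured RNA gene as the nearest annotated 5' end: 1 lay at -471 bp from the 5' end of the piRNA gene 21ur-10279 (1601), 1 at 326 bp from that of 21ur-15698 (1577), and 1 at 1895 bp inside zip-7 (1410), which encodes a bZIP-family protein.

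The RNase P RNA gene rpr-1 (547) and the RNase MRP RNA gene mrpr-1 (242) were the 2 occupied genes of 3 further named polymerase III genes (66.7%, adjusted p = 0.00442, Fisher's exact test). The remaining RNA classes gave low shares or none. Of 261 miRNA genes, 16 were occupied (6.13%, adjusted p = 0.00307, Fisher's exact test). With replicate 1's own list the share was 2.68%, which did not pass the same exact test (adjusted p = 0.0911). Of 7761 other non-coding RNA genes, 451 were occupied (5.81%, adjusted p = 4.29e-38, exact test). Among those with no short structured RNA gene within 500 bp the share was 1.99% and did not exceed the background. Pseudogenes were occupied at 27 of 2128 (1.27%, adjusted p = 0.000709, exact test), below the background. Their share was near the 1.32% mean of circular shifts of the summits (adjusted p = 1, permutation test). That comparison is with shifted summits and not with protein-coding genes, so it does not decide the call. No peak was assigned to 12 SL1 RNA genes (upper bound of the 95% interval 26.5%), 16 5S rRNA genes (20.6%), 4 other rRNA genes or 100 antisense RNA genes, and 1 of 194 lncRNA genes had one. None of these 5 classes differed from the background at the adjusted threshold. None of the 12 SL1 windows and 3 of the 16 5S windows had at least 50% unique sequence. The ranked list held 4 peaks near 5S genes with an IDR of at most 0.01 that the thresholded list lacks, the highest with a signal value of 215, a count made after the data were seen.

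**Figure D1:**
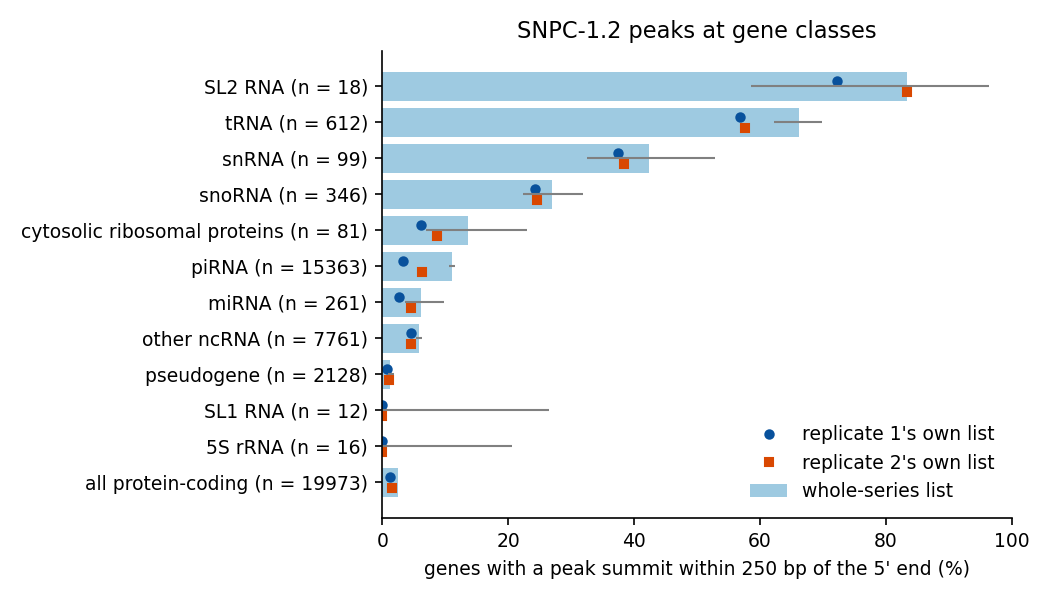
Percent of genes of each class or list (y axis, with the number of genes) that have a peak summit within 250 bp of the 5' end (x axis). Bars give the whole-series list with exact 95% intervals as grey lines, circles replicate 1's own list and squares replicate 2's own list; SL2 RNA and tRNA genes reach 83.3% and 66.2% against 2.48% for all protein-coding genes.

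Chromosome IV held 1361 of the 2829 nuclear peaks (48.1%). Most of these, 1031, lay in the 2 regions of the chromosome that hold most genes for piRNAs, short germline RNAs that guide silencing: 181 in the first region and 850 in the second. The density was 166 peaks per Mb inside these clusters and 29.2 per Mb on the rest of the chromosome. The count was 2.13 times the mean of 10000 circular shifts along chromosome IV (p = 0.0120, two-sided permutation test). The replicates' own lists gave 475 and 667 cluster peaks, 2.09 and 2.15 times their shifts.

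Of 15363 piRNA genes, 1694 were occupied (11.0%, adjusted p = 1.18e-242, Fisher's exact test), with 3.33% in replicate 1 and 6.23% in replicate 2. That test was set against protein-coding genes of the whole genome. Inside the clusters the piRNA share was 11.8%, near the 10.8% of protein-coding genes there (102 of 941), and no test compared these shares. Outside the clusters 16 of 1159 piRNA genes were occupied (1.38%). This is below the protein-coding background and not different from it by Fisher's exact test (adjusted p = 0.232). A summit within 250 bp of a piRNA 5' end was found for 593 of the 1031 cluster peaks. Shifting the summits by 1 to 20 kb gave a mean of 610 (central 95% 584 to 636), so this count was not above what the gene density of the clusters gives. At distances chosen after the data were seen, the counts were above the shifts within 50 bp (258 against 195 to 244) and 100 bp (415 against 351 to 408), and below them within 500 bp (675 against 697 to 744; adjusted p = 0.00492, 0.0274 and 0.00291, permutation tests). The highest-signal occupied piRNA genes, 21ur-5470, 21ur-3160 and 21ur-15018, shared their peaks with F02H6.t1 and Y73F8A.1175.

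**Figure D2:**
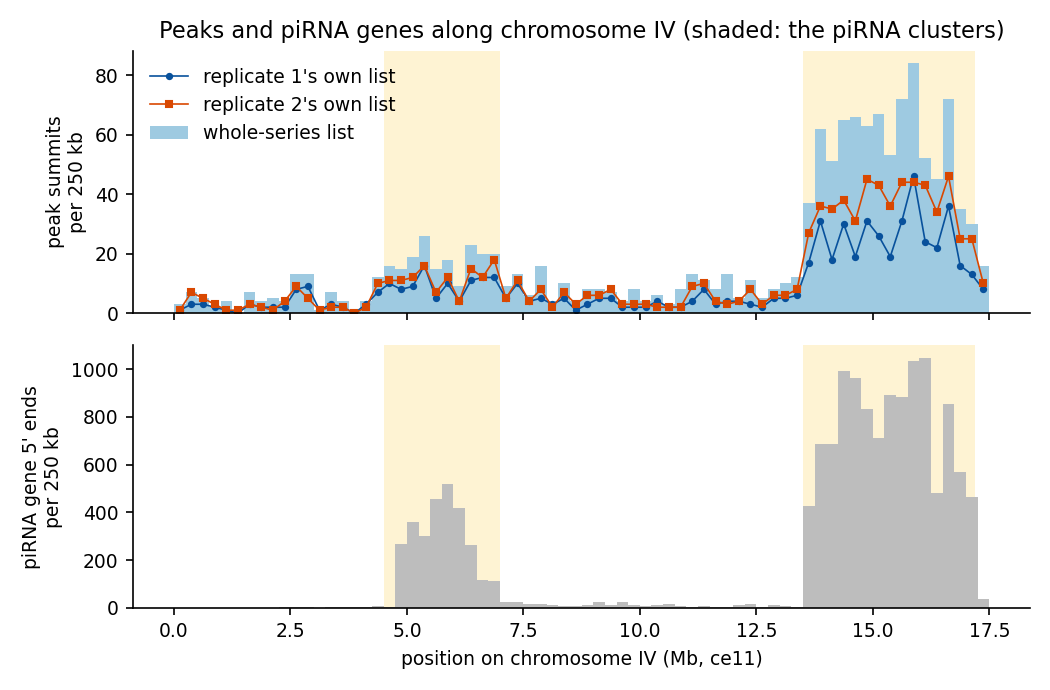
Peak summits per 250 kb (upper y axis) and piRNA gene 5' ends per 250 kb (lower y axis) along chromosome IV in Mb (x axis), with the piRNA clusters shaded. Bars are the whole-series list, circles and squares the replicates' own lists; the fullest bin holds 84 summits.

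Protein-coding genes for the translation machinery were occupied more often than other protein-coding genes. Of 81 cytosolic ribosomal protein genes, 11 were occupied (13.6%, 95% interval 6.98 to 23.0; replicates 7.41% ± 1.75, SD, n = 2), among them rpl-7A (278, with a non-coding RNA gene within 500 bp), rpl-12 (164) and rps-20 (154, with no replicate 2 call within 250 bp). Their share rose to 44.4% with a window of 500 bp and 38.3% with any overlap of the peak, and was 8 of 66 (12.1%) with no short structured RNA gene within 500 bp. Of 33 translation factor genes, 5 were occupied (15.2%), among them eef-1G (149), eef-2 (137) and eef-1B.2 (83.0), which encode elongation factors. Of 72 histone genes, 6 were occupied (8.33%), including his-67 and his-68, which share 1 peak (265), and his-63 (182, with a non-coding RNA gene within 500 bp). Fisher's exact tests gave adjusted p = 1.82e-05 for ribosomal protein genes, 0.00326 for translation factors and 0.0199 for histones. When adjusted over the list alone, meaning the 15 protein-coding lists, these were 3.76e-05, 0.00618 and 0.0335. The translation factor and histone calls were lost when genes within 500 bp were counted once (adjusted p = 0.0506 and 0.128, exact tests), as they were with a window of 100 bp, and replicate 1's own list held 1 translation factor gene. Within the 500 highest peaks the ribosomal protein share was 1.23%, which no longer passed. The median histone gene had unique sequence over 10.4% of its window. Among histone genes with at least 50% unique sequence, 6 of 31 were occupied (19.4%, odds ratio 9.35, adjusted p = 0.000307, Fisher's exact test).

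Chemoreceptor and nuclear hormone receptor genes were occupied less often than other protein-coding genes. For serpentine chemoreceptors, which are expressed in sensory neurons, the count was 6 of 1175 (0.511%, adjusted p = 7.82e-07 by Fisher's exact test, 2.83e-06 adjusted over the list alone), among them srw-95 (231) and sru-9 (134, with no replicate 1 call within 250 bp). For nuclear hormone receptors it was 1 of 269 (0.372%, adjusted p = 0.0339 by the same exact test, 0.0491 adjusted over the list alone), the gene nhr-47 (108, with a non-coding RNA gene within 500 bp). Neither list passed a permutation test by circular shifts, which keep the clustering of peaks (adjusted p = 0.126 and 0.738). That test compares with shifted summits, whose mean shares lay below those of other protein-coding genes, so it does not decide either call. The other lists did not pass the exact test at the adjusted threshold: 3 of 26 Sm, LSm and splicing factor genes (adjusted p = 0.0501), 3 of 27 germline genes (0.0519), 1 of 17 intestine genes (0.505) and 2 of 164 hypodermis and cuticle genes (0.617) were occupied. No gene was occupied among 16 of the piRNA pathway, 31 major sperm protein, 13 body muscle, 15 neuronal and 14 heat shock genes. In the list of SNAPc and TBP genes, 1 of 8 was occupied (adjusted p = 0.280, exact test), snpc-3.4 with 102. The annotated gene snpc-1.2 (III, 13165659 to 13169541) had no thresholded peak, and only a ranked call of 5.03 in replicate 1.

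Among protein-coding genes with no non-coding RNA 5' end within 250 bp of the summit, the highest peak lay at -227 bp from the 5' end of eelo-2 (IV, 17250131 to 17254964; 1166, with 554 and 613 in the replicates). Next came ntl-11 (961), a CCR4-NOT complex gene, Y17G9B.5 (665), the THO complex gene thoc-7 (640), W03F8.4 (634, with no replicate 1 call within 250 bp), and tebp-2 (494), which encodes a telomere-binding protein. The paired Hsp70-family genes F44E5.4 and F44E5.5 on chromosome II shared a peak of 539, but under 50% of their windows was unique sequence. Of these 8 genes, 5 lay inside the piRNA clusters and 1 elsewhere on chromosome IV.

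Protein-coding genes on the X chromosome were occupied less often than autosomal ones: 20 of 2731 (0.732%) against 476 of 17242 (2.76%). The odds ratio was 0.260 (p = 6.56e-13, two-sided Fisher's exact test), and the replicates' own lists gave 0.325 and 0.124. Part of this odds ratio rests on chromosome IV, which held 194 of the 476 occupied autosomal genes (5.91% of its genes). Shares on the other autosomes ran from 1.44% (V) to 2.99% (III), each above that of X. Genes of the tRNA class did not share that direction, with 197 of 276 (71.4%) occupied on X and 208 of 336 (61.9%) on autosomes (odds ratio 1.53, p = 0.0161, Fisher's exact test, a comparison chosen after the data were seen).

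Signal values were higher at peaks of the short structured RNA classes. Against all other peaks of the whole-series list, the median was 2.13 times as high at snRNA peaks (228 against 107; 44 peaks), 2.09 times at snoRNA peaks (222 against 106; 94 peaks), 1.75 times at tRNA peaks (179 against 103; 373 peaks). It was 1.59 times as high at 404 peaks near other non-coding RNA genes, most of which are shared with other RNA classes, since assigning each peak to 1 class leaves 136 for these genes, miRNA and lncRNA genes and pseudogenes together; this fold was not measured away from short structured RNA genes. All had an adjusted p of 3.2e-05 in two-sided permutation tests, resting on the smallest p that 100000 resamples give, 2e-05. The 16 SL2 RNA peaks were 1.89 times as high (adjusted p = 0.00275, permutation test), a call that neither replicate's own list kept (1.41 and 1.09 times). Peaks at piRNA genes were lower, 0.889 times (adjusted p = 3.2e-05, permutation test), while those outside the clusters were at 1.22 times and did not pass. Peaks at miRNA genes (1.19 times, adjusted p = 0.285) and protein-coding genes (1.02 times, 0.474) were not told apart from the rest by the permutation test. Within the 500 highest peaks, a set chosen on the signal itself, the tRNA fold was 0.961 and the piRNA fold 1.29.

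Signal at tRNA and snRNA genes differed between the piRNA clusters and elsewhere. The 38 occupied tRNA genes inside the clusters had a median signal value of 807 against 178 for the 367 outside, a ratio of 4.55 (bootstrap 95% interval 4.07 to 5.44), with 4.03 and 4.55 in the replicates. For snRNA genes the ratio was 2.49 (1.53 to 4.56; 10 and 32 genes). For snoRNA genes it was 5.19, but the interval of 0.951 to 9.96 includes 1 (11 and 82 genes). The replicates' own lists gave 4.56 (1.32 to 9.04) and 5.13 (1.12 to 9.49) for snoRNA genes, so whether the interval includes 1 depended on the list. Over all peaks the ratio was 0.963. More tRNA genes were also occupied inside the clusters, 38 of 41 (92.7%) against 367 of 571 (64.3%; adjusted p = 9.25e-05, Fisher's exact test). Protein-coding genes with no non-coding RNA gene within 500 bp rose too, from 329 of 17402 outside (1.89%) to 71 of 443 inside (16%; odds ratio 9.90 against 7.04 for tRNA genes, adjusted p = 1.73e-39, exact test). These inside and outside comparisons were chosen after the list of highest peaks had been seen.

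**Figure D3:**
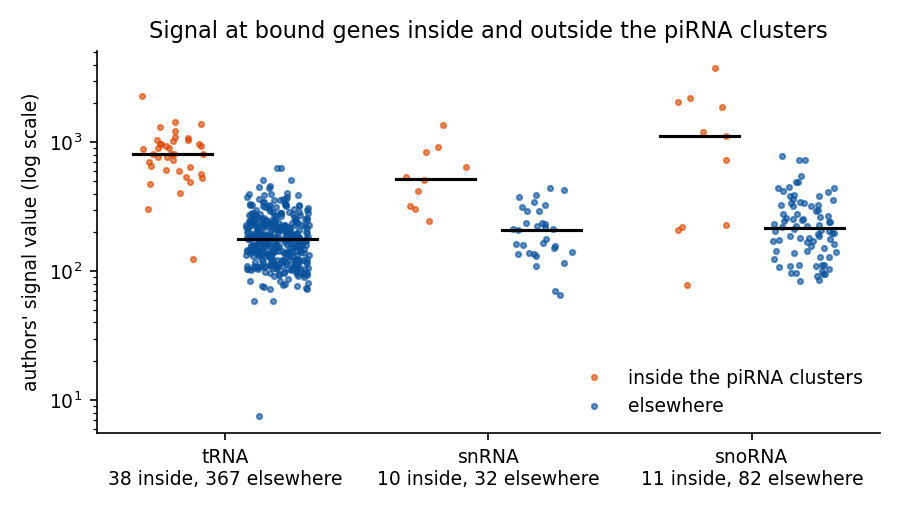
The authors' signal value of the peak (y axis, log scale) at each occupied tRNA, snRNA and snoRNA gene (x axis), inside the piRNA clusters (orange) and elsewhere (blue), in the whole-series list. Each point is 1 gene and horizontal lines are medians, 807 inside against 178 elsewhere for tRNA genes.

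Summits lay inside tRNA genes and upstream of snRNA and snoRNA genes. The median position relative to the 5' end was 18 bp downstream for tRNA genes (interquartile range 2 to 34), whose promoter elements lie within the gene. It was -20 bp for snRNA genes (-27 to 10.8), -27 bp for snoRNA genes (-45 to 2) and -7 bp for SL2 RNA genes (-19 to 49.5). The tRNA median exceeded that of snRNA genes by 38 bp and that of snoRNA genes by 45 bp (adjusted p = 6e-05 each, from the smallest p that the permutation test allows), and that of SL2 genes by 25 bp (adjusted p = 0.0120, permutation test). The differences of snoRNA and of SL2 from snRNA genes did not pass the permutation test (-7 bp, adjusted p = 0.194, and 13 bp, 0.211), and snoRNA and SL2 genes were not compared with each other. At piRNA genes summits were spread over the window (median 34.5 bp, interquartile range -71.8 to 130) and not separated from snRNA genes (adjusted p = 0.0953, permutation test). At protein-coding genes the median was -108 bp (-176 to 0.5). In the replicates' own lists the tRNA median was 17.5 and 22 bp, the snRNA median -10 and -16.50 bp, and the snoRNA median -31 bp in both. The SL2 median was 2 and -9 bp, so its side of the 5' end depended on the list, and the piRNA median 58 and 37 bp.

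**Figure D4:**
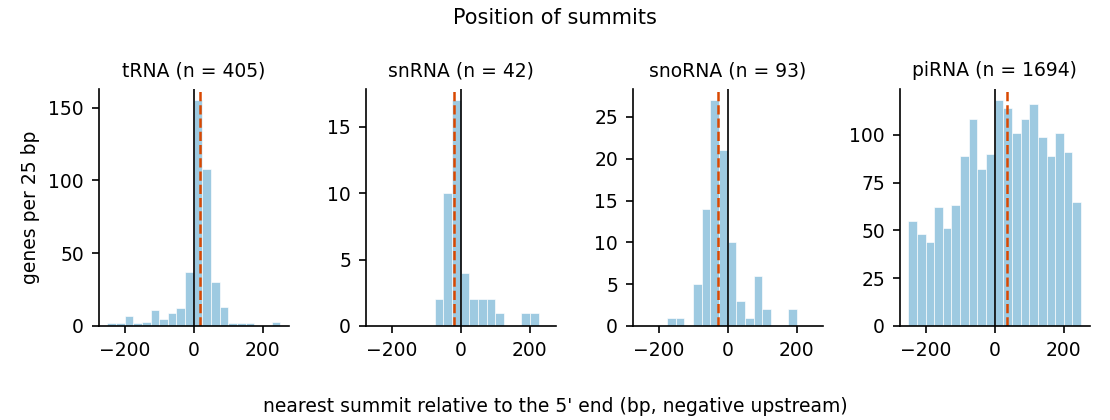
Number of occupied genes per 25 bp (y axis) by the position of the nearest summit relative to the gene's 5' end in bp, negative upstream (x axis), for 405 tRNA, 42 snRNA, 93 snoRNA and 1694 piRNA genes of the whole-series list. Solid lines mark the 5' end and dashed lines the medians, 18, -20, -27 and 34.5 bp.

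Sequence words of tRNA promoters marked the summits of tRNA peaks. Over all 2829 nuclear peaks, 1034 words of 8 bases were more frequent within 75 bp of the summit than in flanks 500 bp away and 397 less frequent (adjusted over 32896 words, Fisher's exact test). Peaks at tRNA genes alone gave 642 and 45. In these the word GGGTTCGA, part of the B box, was found at 32% of summits against 2.42% of flanks, and CTGAGCTA at 28.2% against 1.08%. The full B box was at 58.1% of tRNA summits against 2.42% of flanks (adjusted p = 1.38e-69, Fisher's exact test). These peaks were selected for lying near tRNA genes, which carry the B box, so these contrasts with flanks follow largely from the selection. Over all 2829 summits the full B box was at 257 (9.08%) against 0.46% of flanks, and 216 of these 257 were tRNA summits. Peaks at snRNA (44), SL RNA (16) and snoRNA (94) genes gave no word of 8 bases past the threshold. The full B box was at 7 of 94 snoRNA summits (7.45%) and none of their flanks (adjusted p = 0.0278, Fisher's exact test), and at no snRNA or SL RNA summit. CTGTTTCA, the core of the element upstream of piRNA genes, was at 29.0% of the summits of piRNA peaks against 14.2% of their flanks (adjusted p = 6.04e-09, exact test). That set was selected for lying near piRNA genes. Over all 1031 cluster peaks, a set added after the data were seen, CTGTTTCA was at 16.9% against 10.6% (odds ratio 1.72, adjusted p = 0.000145, exact test). This wider set was defined by region and not by distance to piRNA genes, but it holds the piRNA peaks of the clusters. The word was at 174 of its summits and at 169 of the 583 piRNA summits, so most of its hits lie at piRNA peaks. Cluster peaks with no 5' end within 250 bp held the word at 4 of 304 summits (1.32%), a set selected for lying away from piRNA genes, so its summits and flanks are not compared.

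By place, 23.5% of the nuclear peaks lay inside a gene but away from any 5' end, 20.6% near a piRNA gene, 18.7% between genes, 13.7% near a protein-coding 5' end, 13.1% near a tRNA gene, 4.81% near another non-coding RNA gene, 3.32% near a snoRNA gene, 1.56% near an snRNA gene and 0.566% near an SL RNA gene. The tRNA share was 22.4% in replicate 1's own list and 18.3% in replicate 2's, and the piRNA share 12.6% and 19%, so both moved with the list used.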

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

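The items in this part were found while the peak lists were compared with each other, and no test was made of either.

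The mitochondrial genome held 13 peaks of the whole-series list, which no comparison of gene classes or regions used. Their signal values started at 475 and had a median of 1555, and the highest of them exceeded the highest nuclear value, 3755. Replicate 1's own list held 17 such peaks and replicate 2's own list 18. They stood out as signal in data outside the nuclear comparisons.

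The whole-series ranked list held 95 peaks with a global IDR of at most 0.01 that the thresholded list lacks. Their median signal value was 121 and the highest 3120, on chromosome X at 15811109. Of these, 11 lay in the piRNA clusters and 5 near a short structured RNA gene: 4 at 5S rRNA genes, a class with 0 of 16 genes occupied in the thresholded list, and 1 at a snoRNA gene on chromosome IV, with a signal value of 1358. The conservative list lacks 88 such peaks, replicate 1's own list 54 and replicate 2's 65. The reason for their removal is not given in the sources used here.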

How the results depend on the processing

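Of 570 results under alternatives, 479 were kept, 30 were no longer past the threshold, 13 newly passed, 38 moved and 10 reversed. A tested result was kept if its direction and its side of the threshold stayed. Shares of peaks and the replicate correlation were kept if they lay within the 95% interval of the main value. Counts of peaks and words were kept if they lay within 1.5-fold of the main count. A direction that passed no threshold under either setting was counted as kept. The IDR limit of 0.01 removed no peak, since every thresholded peak already met it, so its 45 results show nothing about stability. The limit of 0.001, the settings by distance to clusters or short RNA genes, the leave-outs for summit position and words, and the flanks with as many word positions were chosen after seeing the data. Unless a reason is given, the cause was not tested.

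An IDR of at most 0.001 left 1254 peaks. It gave shares of 24.0% tRNA, 14.3% piRNA, 6.20% snoRNA and 3.06% snRNA peaks. Occupancy of pseudogenes (0.752%), translation factors (6.06%) and nuclear hormone receptors (0%) no longer passed, nor did the SL2 signal fold (1.25). The protein-coding signal fold reversed to 0.900 and passed (adjusted p = 0.0234, permutation test), which the fold of the main list did not.

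The 500 highest peaks, fewer and chosen on the signal, were 30.8% tRNA, 10.8% snoRNA, 7.4% piRNA and 5.2% snRNA peaks. Occupancy no longer passed for miRNA (0.766%), ribosomal protein (1.23%), histone (2.78%), nuclear hormone receptor (0%) and chemoreceptor genes (0.0851%). For pseudogenes (0.423%) and translation factors (0%) it changed direction, but neither passed in the new direction. Signal folds fell to 1.12 for both snRNA and snoRNA peaks, which no longer passed, and reversed for tRNA (0.961), other non-coding RNA (0.959) and piRNA (1.29) peaks.

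A window of 100 bp, which admits fewer summits, left pseudogenes (0.846%), histones (2.78%), translation factors (6.06%) and nuclear hormone receptors (0.372%) short of the threshold. It gave 14.5% piRNA and 28.7% intergenic peaks and medians of -28 bp (snoRNA), 9 bp (piRNA) and -27 bp (protein-coding). A window of 500 bp raised ribosomal protein genes from 13.6 to 44.4%, the snRNA share at that window, and splicing factors to 23.1% and germline genes to 14.8%, both then past the threshold. It gave 23.1% piRNA and 12.5% intergenic peaks and medians of -26.5 bp (snoRNA) and -155 bp (protein-coding). Any overlap of the peak gave 38.3% for ribosomal protein genes and also 23.1% and 14.8% for the other 2 lists.

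Circular shifts left the shares as they are and changed the comparison from protein-coding genes to shifted summits. Splicing factors (11.5%) and germline genes (11.1%) passed. Pseudogenes (1.27%), nuclear hormone receptors (0.372%) and chemoreceptors (0.511%) did not, where the shift means lay below the protein-coding shares. With the conservative list, SNAPc and TBP genes (25%), splicing factors (11.5%) and germline genes (11.1%) passed. With 1 gene per locus, splicing factors (15%) passed, and histones (7.5%) and translation factors (11.1%) did not.

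Outside the piRNA clusters, piRNA occupancy (1.38%) and the piRNA signal fold (1.22) changed direction, but neither passed in the new direction. Nuclear hormone receptors (0.379%) no longer passed there. With no short structured RNA gene within 500 bp, other non-coding RNA occupancy (1.99%) changed direction without passing, and nuclear hormone receptors (0.373%) fell short. The replicate signal correlation was 0.573 at an IDR of at most 0.05, a set selected for agreement between the replicates, and 0.373 at protein-coding 5' ends.

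Leaving out a replicate means using the other replicate's own list, which holds fewer reads and peaks by construction (1428 to 1755). Occupancy then ran from 2.68 to 4.6% (miRNA), 0.705 to 0.987% (pseudogenes), 0 to 25% (SNAPc and TBP), 11.5% in both (splicing factors), 3.03 to 9.09% (translation factors) and 0.372% in both (nuclear hormone receptors). By the exact test, splicing factors newly passed in both lists (adjusted p = 0.00991 and 0.0162), and SNAPc and TBP genes without replicate 1 (0.0151). Calls lost by the exact test were pseudogenes (0.0813 and 0.0915) and nuclear hormone receptors (0.664 and 0.232) in both, and miRNA (0.0911) and translation factors (0.603) without replicate 2. Peak shares ran from 2.13 to 2.62% (snRNA), 18.3 to 22.4% (tRNA), 5.07 to 6.24% (snoRNA) and 12.6 to 19% (piRNA). The SL2 signal fold ran from 1.09 to 1.41 and passed in neither (adjusted p = 0.736 and 0.0921, permutation test). Median summit positions ran from 17.5 to 22 bp (tRNA), -16.50 to -10 bp (snRNA), -9 to 2 bp (SL2, reversed without replicate 2), and 37 to 58 bp (piRNA), and were -31 bp (snoRNA) and, rounded, -1.2e+02 bp (protein-coding) in both. Words higher at summits numbered 616 to 766.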

Other observations

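The tests of tRNA subtypes, tRNA pseudogenes and word pairs, of the same share of genes in both regions, and of distances to piRNA genes other than 250 bp, were chosen only after the result was seen; the remaining tests of this part had their bounds written beforehand.

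Occupancy of tRNA genes was spread over the amino acids. It ran from 5 of 14 tRNA-Phe genes (35.7%) to 34 of 42 tRNA-Pro genes (81.0%), apart from 5 genes with no type given, of which 0 were occupied, and the single tRNA-Sec gene, which was. No type differed from the others after adjustment over 22 tests (smallest adjusted p = 0.0943, Fisher's exact test). Pseudogenes named as tRNA genes were occupied at 15 of 209 (7.18%), less often than tRNA genes (odds ratio 0.0395, p = 4.70e-55, Fisher's exact test).

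Many peaks had no annotated 5' end within 250 bp: 1194 of 2829 (42.2%), of which 304 lay in the piRNA clusters and 30 were among the 100 highest. A pair of words read from summit sequences, CCGCCGACA followed within 30 bp by GGTTCCGC, occurred at 52 sites inside the clusters, of which 39 (75%) had a summit within 150 bp, and at 87 sites outside, of which 2 (2.30%) did (p = 7.85e-21, Fisher's exact test). Among sites with at least 50% unique sequence the counts were 18 of 27 and 1 of 51 (p = 3.59e-10, Fisher's exact test). The related pair GGCCGACA and GGTTCCGC had a summit at 7 of 8 sites inside and at 27 of 248 sites outside (10.9%; p = 2.96e-06, exact test). The words were chosen from these same summits, so these shares are not independent evidence.

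In a pattern first noticed among the highest peaks, occupied tRNA genes had 4.55 times the median signal inside the piRNA clusters (4.07 to 5.44). Regional background cannot be told apart: protein-coding 5' ends with no non-coding RNA gene nearby had a ratio of 1.77 (1.2 to 2.18), which met the bound set against it, but only genes past the peak threshold enter that ratio, and 16% passed inside against 1.89% outside. With the same share of all genes taken in both regions it was 5.26 (3.78 to 6.45; 8 genes inside), against 5.35 (4.55 to 6.03) for tRNA genes. Unique sequence around the gene is argued against by a ratio of 5.16 (4.31 to 6.04) at tRNA genes with at least 90% unique sequence. A repeat of the short gene alone could still meet that limit, so it is not decided. Signal of neighbouring piRNA genes is argued against by 4.44 (3.68 to 5.42) at tRNA genes with no piRNA gene within 500 bp. For snoRNA genes the ratio was not resolved; no biological explanation was tested, and open chromatin or input signal in the clusters, not analysed here, may contribute.

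Of 612 tRNA genes, 207 had no peak. Repeated sequence around the gene is argued against as the whole cause, by the bound of 90% or more. Of tRNA genes with at least 50% unique sequence, 66.9% (63.0 to 70.7) had a peak. But 605 of the 612 genes met that limit, over windows reaching 250 bp on each side. The median window was 92.0% unique with and without a peak. A repeat of the short gene alone would meet the limit too, so repeats within the gene are not decided. The threshold of the peak list is also argued against as the whole cause, by the bound of 80% or more. Of the genes without a peak, 40.6% (33.8 to 47.6) had a call in both ranked lists, against 96.8% of those with one. That share is above the 15.6% of protein-coding genes without a peak, so for part of the genes the threshold may matter. No biological explanation was tested.

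Inside the clusters, 593 peaks lay within 250 bp of a piRNA 5' end, within the range that chance proximity gives after shifts of 1 to 20 kb (584 to 636). Within 50 bp there were 258, above the 195 to 244 of the shifts (adjusted p = 0.00492 over 16 tests, permutation test), and within 100 bp 415 (351 to 408), while within 500 bp there were 675, below the shifts (697 to 744, adjusted p = 0.00291, permutation test). Cluster peaks with no short structured RNA gene within 500 bp gave 254 against a mean of 205 within 50 bp and 410 against 358 within 100 bp (adjusted p = 0.00291 each, permutation test), but 641 against 677 within 500 bp (0.00492). This is consistent with some peaks lying close to piRNA 5' ends, as a hypothesis found and tested on the same data. No biological explanation was tested.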
